A study of Homo sapiens with 12 samples.

How the data were processed

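Total RNA of SKOV3 cells was extracted with Trizol, amplified to biotinylated cRNA with an Ambion MessageAmp kit and hybridised to Illumina bead arrays, per the labels' protocols, which give an RNA integrity number of 10 for every sample. The 12 samples fall into 4 groups of 3 by the labels: mock cells untreated, mock cells with TGF-β, VEPH1 cells untreated and VEPH1 cells with TGF-β. The main values are the log2 values per probe deposited by the authors in the series' value table, 47323 probes on 12 arrays. Their normalization and any background step are not given in the sources used here. All 12 columns have the same mean, minimum and maximum and medians of 7.29, as quantile normalization between arrays gives, and nothing was normalized again for the main results. A second table holds bead signals that were not normalized, in 24 columns named by 12 positions of 1 chip; no label ties a position to a sample, so these 24 columns were not used here. Scanner values of named samples and detection p-values were thus not used, and the deposited values could not be set against scanner values; their base was taken as log2 from their range.

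The design fixed before the data were examined foresaw neqc and detection p-values, which need scanner values. The main values were therefore the deposited ones, and a probe counted as above background where its value exceeded 7.40, the 95th percentile of 587 probes of olfactory receptor, keratin-associated, taste receptor and vomeronasal receptor genes, families not expected in these cells. This rule was chosen after the distribution of the values was seen and before any groups were compared. A probe was kept if it was above that level on all 3 arrays of at least 1 group, which left 17761 probes; 38.3% of all values were above it. Of the probes, 30113 had 1 gene symbol, 8 several and 17202 none in the probe table used here. Symbols were checked through Entrez identifiers against a RefSeq gene table of GRCh38.p14, which matched 30074 and changed none. Each gene was represented by its kept probe with the highest mean over all arrays, which gave 10781 genes. Of these, 2372 had several kept probes: of the 918 such genes called between the untreated lines, 129 had another probe of opposite sign, and in 7 that probe was called too.

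A linear model with a mean per group was fitted to all 12 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with 8 residual degrees of freedom, and Benjamini-Hochberg adjusted p under 0.05 was the threshold. Contrasts were the TGF-β response in each line, their mean, their difference (the interaction), and VEPH1 minus mock cells untreated and after TGF-β. Where every array of 1 group was below background, the brighter group's mean was set against the mean of the higher of the background level and the dim probe's own value, and the fold is given as "at least". Where only a group's mean was below background, no size is given, or LIMK2's is given with its limit. The size of the response was compared over genes past the threshold for the mean response, as the median of the VEPH1 response minus the mock response in the direction of the gene's mean response, with fry on the interaction contrast. Before the data were examined 26 gene lists were fixed; each was tested with fry, two-sided, adjusted over the 26 lists of a comparison, and with camera at a preset correlation of 0.01 and at an estimated one. Fry asks whether a list's genes move, on balance, one way. With the estimated correlation the calls that held were the BMP-shared list in both responses, in their difference and between the treated lines, the early SMAD2/3 targets in mock cells, and the β-catenin/TCF targets and ovarian markers between the treated lines. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

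Genes were named by a rule fixed beforehand: per comparison, among genes past the threshold whose groups did not overlap (10% of genes for 3 against 3 by chance), these were the 10 largest rises and 10 largest falls. For the difference of the responses, up to 10 genes with the smallest p among those past the threshold were named. Any member of a fixed list could be named, and VEPH1 always. Array correlations within groups were 0.992 to 0.997 over the tested genes and no columns were identical. Numbers shared by replicates were checked as a pairing. The deviations from group means of samples with the same number correlated at 0.19 to 0.33 for the TGF-β comparison in mock cells, 0.36 to 0.51 in VEPH1 cells, 0.16 to 0.25 between untreated lines and 0.14 to 0.37 between treated lines, all over 0.1. By this cut of 0.1 the numbers were taken to pair the samples of these comparisons. Samples with unlike numbers were not compared, so how often chance passes the cut is not known. The pairing comes from the data, as the labels name no shared day or culture. Over all pairs of groups the lowest was −0.04, so the numbers do not pair the 4 groups as a whole. Results of the fit with the replicate number as a block are given beside a reported result where they change its call, or a count by over 1.5 times.

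The steps were tested on simulated data with the real genes' means and spreads and 200 changed genes among 10781. For TGF-β in mock cells 77.6% of genes changed by 0.5 and 100% of those changed by 1 on the log2 scale were recovered, with 17 unchanged genes called. For the difference of the responses 44.8% and 98.5% were recovered. A VEPH1 response 0.5 times the mock response was called in 20 of 20 draws, and equal responses in 0 of 20. The mock changes in these draws were 1 on the log2 scale, and the noise was independent between genes and arrays. The draws therefore do not show how often fry calls equal responses where genes or arrays are correlated. Alternatives were tried for the filter, the probes of a gene, the samples in the fit, the replicate block, array weights, the variance model, the fold threshold, the set test, the choice of response genes and each sample left out. Background correction by normexp with the same gene families as negative controls (offsets 16 and 50) and centring on the median of tested genes were added after the data were examined. The precision is limited by the number of arrays.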

Results

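Transcript levels were measured on 12 Illumina bead arrays in SKOV3 cells, a human ovarian carcinoma line, that had been made to carry either a cadmium-inducible, Flag-tagged VEPH1 construct or a mock vector. VEPH1 encodes a pleckstrin homology domain protein, the human counterpart of Drosophila melted. Both kinds of cells were profiled untreated and after 3 hr with TGF-β, a cytokine that acts through SMAD transcription factors, which gave 4 groups of 3 arrays. Of 47323 probes, 17761 were above background in at least 1 group, and 10781 genes were tested, each through its brightest probe. The labels do not say whether the 3 replicates of a group were separate cultures, so p-values measure only the spread between these arrays, which may be technical. The labels also do not give the number of separately transfected lines or the arrays that received cadmium, so a difference between VEPH1 and mock cells can come from VEPH1 or from any other difference between the cells. Changes are log2 fold changes with their standard errors (SE) from limma, with 3 arrays per group.

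VEPH1 itself was read first, as a check of the labels. Its probe read 6.93 to 7.11 on the log2 scale on the 6 mock arrays, below the background level of 7.40 on each. It averaged 11.87 ± 0.09 (SD, n = 3) in untreated and 11.80 ± 0.12 in treated VEPH1 cells. VEPH1 was at least 22.2-fold higher in untreated VEPH1 cells (limma, adjusted p = 7.13e-16) and at least 21.1-fold higher after TGF-β (adjusted p = 9.87e-16), with each bound taken against the background level.

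**Figure D1:**
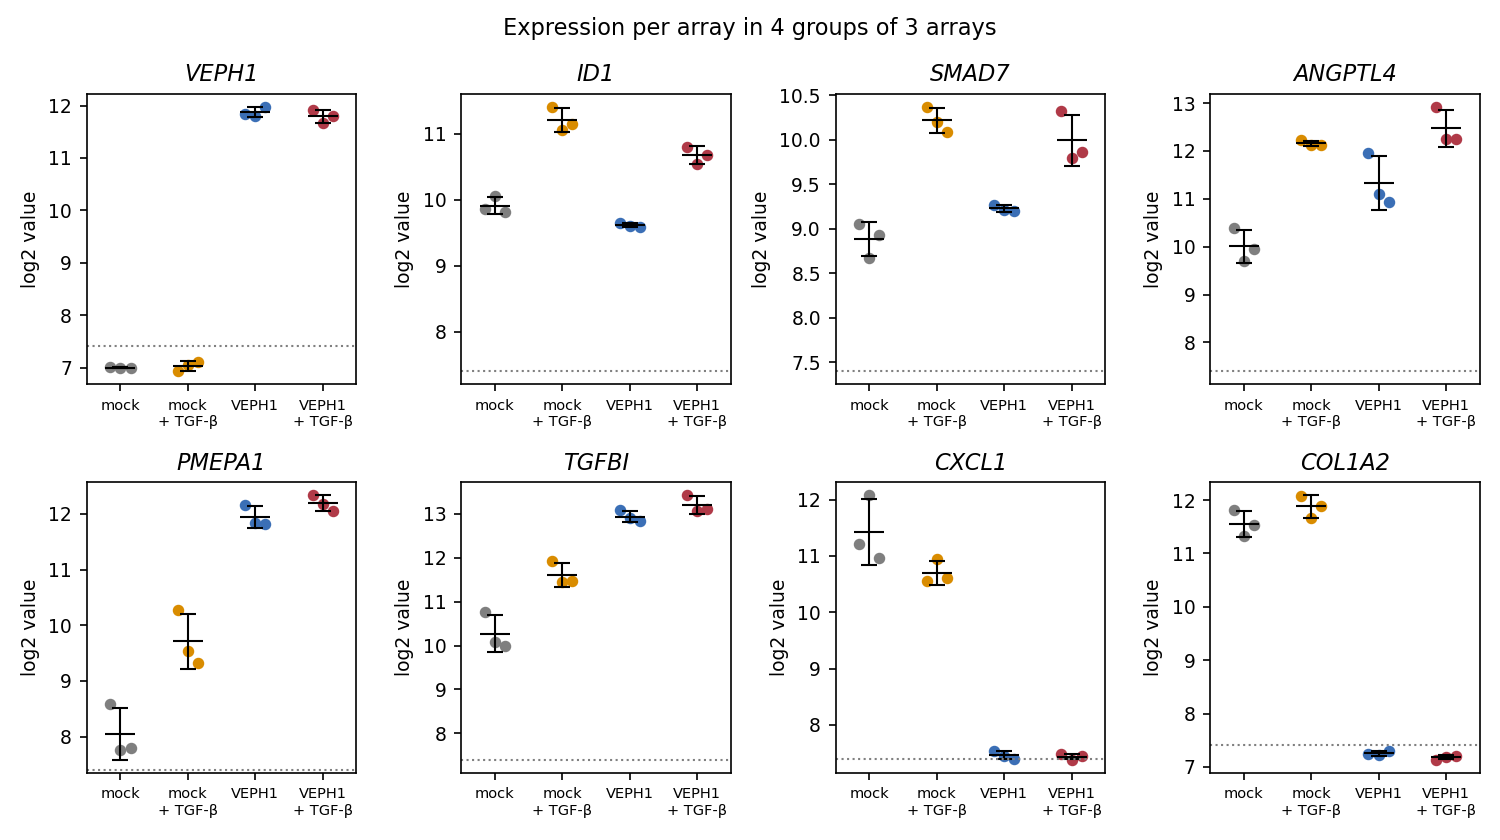
Log2 value (y axis) of 8 genes on each array (dots) in the 4 groups (x axis), with the mean and SD of 3 arrays per group in black and the background level of 7.40 as a dotted line. VEPH1 was below the dotted line in all 6 mock arrays, ID1, SMAD7, ANGPTL4, PMEPA1 and TGFBI were higher with TGF-β in mock cells, and CXCL1 and COL1A2 were near or below background in VEPH1 cells.

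The first comparison asked what TGF-β does to SKOV3 cells without the VEPH1 construct. In mock cells TGF-β raised SMAD7 and PMEPA1, which restrain its own pathway, and several ID genes. ANGPTL4, which encodes a secreted inhibitor of lipoprotein lipase, had the largest fitted rise, 2.15 (SE 0.23) or 4.42-fold. It was followed by PMEPA1 (1.66, SE 0.22), a membrane protein that binds SMADs, and ID3 (1.52, SE 0.17). The matrix protein gene TGFBI (1.34, SE 0.17), SMAD7 (1.33, SE 0.13), the inhibitory SMAD, and ID1 (1.29, SE 0.10) were next. The glycolytic regulator PFKFB3 (0.98, SE 0.10), GADD45B (0.97, SE 0.14) and RHEX (1.05, SE 0.15) also rose. FOXS1, not above background in untreated mock cells, was at least 1.83-fold higher. The largest falls were in PLEKHF1 (−0.92, SE 0.10), the transcription factor gene CEBPD (−0.89, SE 0.14), the metalloproteinase gene ADAMTS1 (−0.83, SE 0.08), the chemokine genes CXCL2 (−0.81, SE 0.12) and CCL20 (−0.76, SE 0.10), and BDNF (−0.74, SE 0.09). CAVIN2 (−0.72, SE 0.10), PAX8 (−0.69, SE 0.10), a Müllerian lineage factor, the tight junction gene CLDN1 (−0.69, SE 0.12) and PLD6 (−0.66, SE 0.08) fell as well. In all, 116 genes passed an adjusted p of 0.05 in limma, of which 72 rose and 44 fell. The fit with the replicate number as a block called 216 (134 up, 82 down). The count was 62 without untreated mock replicate 3, 63 without treated mock replicate 1 and 66 without treated mock replicate 3. The adjusted p of CLDN1 was 0.061 without untreated mock replicate 1 and 0.0722 without treated mock replicate 3.

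Among gene lists fixed before the data were examined, the list of genes shared with BMP signalling moved most in mock cells. Of its 7 tested members, 6 rose over all genes tested and 7 when adjusted over the list alone, among them ID2 (0.88, SE 0.12), SMAD6 (0.96, SE 0.09) and SMAD9 (0.65, SE 0.14). ID4, not above background in untreated mock cells, was at least 1.48-fold higher. The set test fry gave this list an adjusted p of 8.43e-08, and camera gave adjusted p = 0.000174 with an estimated correlation. Of 16 tested early SMAD2/3 targets, 6 rose (11 when adjusted over the list alone, 10 with the replicate block): ANGPTL4, PMEPA1, TGFBI, SMAD7, BHLHE40 (0.54, SE 0.07) and JUNB, which was at least 1.35-fold higher. Their median change was 0.49, or 0.45 with members below background at their bounds (fry adjusted p = 0.000691 over 26 lists, and adjusted p = 0.0098 with an estimated correlation).

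Smaller shifts were seen in 3 other lists in mock cells, and none of them passed with an estimated correlation. Of 10 tested NF-κB targets and cytokines, CXCL2 and CCL20 fell, and 3 fell and 1 rose when adjusted over the list alone (fry adjusted p = 0.0335; adjusted p = 0.197 with an estimated correlation; adjusted p = 0.0757 after background correction). CXCL1 (−0.71, SE 0.19, adjusted p = 0.117, or 0.0264 with the replicate block) and CXCL8 (−0.59, SE 0.37, adjusted p = 0.624) did not pass. Probes of the closely related CXCL1 and CXCL2 may share signal. In the FOXO and insulin list of 15, PIK3IP1, which encodes an inhibitor of PI3 kinase, rose (0.64, SE 0.11) and BCL6 fell (−0.36, SE 0.07), the same 1 and 1 when adjusted over the list alone. The list leaned down (median −0.11, fry adjusted p = 0.0306; adjusted p = 0.197 with an estimated correlation). In the metal response list of 7, the zinc exporter gene SLC30A1 rose (0.41, SE 0.07), and 2 rose when adjusted over the list alone. Fry gave an adjusted p of 0.0469, which was 0.0538 with the replicate block, and camera gave adjusted p = 0.197 with an estimated correlation. With the replicate block 11 of the 26 lists passed fry instead of 5. In the 21 lists whose set test did not pass without it, single members did. CCN1 (0.84, SE 0.16), the immediate early gene FOSB (0.89, SE 0.17), the integrin gene ITGAV (0.70, SE 0.10) and the BMP receptor gene BMPR2 (0.56, SE 0.07) rose. The interferon-stimulated gene IFIT2 fell (−0.42, SE 0.10).

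The second comparison asked how cells that express VEPH1 respond to TGF-β. ID1 rose by 1.06 (SE 0.10) or 2.09-fold (limma, adjusted p = 0.000131) and ADAMTS1 fell (−0.53, SE 0.08, adjusted p = 0.0458). These were the 2 genes that passed, with 648 genes at an unadjusted p under 0.05. The fit with the replicate number as a block called 16 genes, 12 up and 4 down. Among these SMAD7 (0.77, SE 0.13, adjusted p = 0.0627 without the block and 0.000718 with it), ANGPTL4 (1.14, SE 0.23, adjusted p = 0.217 and 0.000609) and ID3 (0.67, SE 0.17, adjusted p = 0.403 and 0.000609) rose. So did CCN2, which encodes a matricellular growth factor (0.86, SE 0.25, adjusted p = 0.513 and 0.000157), and IL11 (0.76, SE 0.22, adjusted p = 0.513 and 0.0296). Of the 7 BMP-shared genes, ID1 rose, and 3 rose when adjusted over the list alone (median 0.22, fry adjusted p = 0.000264; adjusted p = 0.0185 with an estimated correlation). Of the 16 early SMAD2/3 targets none passed over all genes and 4 rose when adjusted over the list alone. Their median was 0.21 with a fry adjusted p of 0.134 over 26 lists, 0.000619 with the replicate block, and an adjusted p of 0.1 with an estimated correlation. The call of ADAMTS1 was lost without any 1 of 9 of the 12 arrays, with an adjusted p of up to 0.284.

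The 2 responses were then compared directly, since a gene that passes in one line and not in the other is not thereby shown to differ. The TGF-β response of VEPH1 cells was the smaller one for most response genes. Over the 108 genes that changed on average over both lines (71 up, 37 down; 205 genes with the replicate block), the median change in the direction of the response was 0.49 in mock cells and 0.26 in VEPH1 cells. The response was smaller in VEPH1 cells for 100 of the 108 (92.6%), with a median difference of −0.26 (quartiles −0.46 and −0.13; fry on the interaction contrast, p = 0.000153; permutation of the residuals over the arrays, p = 0.01). Without treated mock replicate 3 the median difference was −0.40. These genes were chosen on the mean of both responses, which favours neither line. PMEPA1 changed by 1.66 in mock and 0.25 (SE 0.22) in VEPH1 cells, and TGFBI by 1.34 and 0.26 (SE 0.17), whereas ID1 changed by 1.29 and 1.06.

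**Figure D2:**
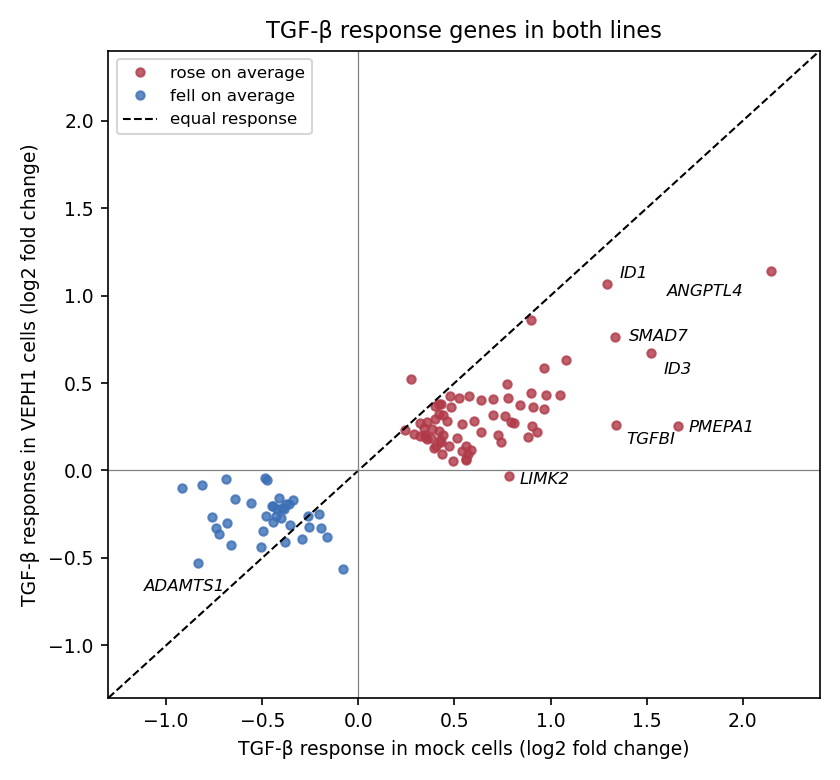
TGF-β response in VEPH1 cells (y axis, log2 fold change) against that in mock cells (x axis, log2 fold change) for the 108 genes that changed on average over both lines, one point per gene, with equal responses on the dashed line. For 100 of the 108 genes the response was smaller in VEPH1 cells, as for PMEPA1 with 1.66 in mock and 0.25 in VEPH1 cells.

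Gene by gene, the difference of the responses passed for 1 gene, LIMK2, which encodes a kinase that phosphorylates cofilin (difference −0.82, SE 0.11, limma adjusted p = 0.0266; 645 genes at an unadjusted p under 0.05). LIMK2 went from 7.28 ± 0.14 to 8.07 ± 0.07 (SD, n = 3) in mock cells and from 7.77 ± 0.03 to 7.74 ± 0.06 in VEPH1 cells. The untreated mock mean lies below the background level of 7.40, so the size of the difference is uncertain, and it was −2.02 after background correction. Its call was lost without any 1 of 9 of the 12 arrays, with an adjusted p of up to 0.153. With the replicate block 7 genes passed, and each changed less in VEPH1 than in mock cells, where 6 rose and PLEKHF1 fell. The block assumes replicate effects shared by all 4 groups, which the numbers did not show as a whole, so these calls are tentative. PMEPA1 (−1.41, SE 0.31, adjusted p = 0.358 without the block and 0.00179 with it) and TGFBI (−1.08, SE 0.25, adjusted p = 0.358 and 0.00179) were among them. ID3 (−0.85, SE 0.24, adjusted p = 0.474 and 0.00248) and FOSB (−0.83, SE 0.24, adjusted p = 0.492 and 0.00463) were too. The BMP-shared list differed as a set (median difference −0.69, fry adjusted p = 4.77e-05; adjusted p = 0.00185 with an estimated correlation). None of the 7 passed over all genes and 6 were lower when adjusted over the list alone. The early SMAD2/3 targets differed by a median of −0.23, with none past the threshold over all genes and 6 lower when adjusted over the list alone. Over 26 lists fry gave an adjusted p of 0.124, or 0.00203 with the replicate block, and adjusted p = 0.131 with an estimated correlation. The housekeeping genes had the same adjusted p of 0.124 and 0.131, with a median difference of 0.14. With the block 4 lists passed fry, among them the housekeeping genes and the β-catenin/TCF targets (adjusted p = 0.0366 each). A pass with the block is thus not particular to TGF-β targets.

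The third comparison set untreated VEPH1 cells against untreated mock cells. Among the largest differences were lower AKR1C2, COL1A2, AKR1C3 and CXCL1 and higher ADAM19, PMEPA1 and CXADR in VEPH1 cells. AKR1C2 (−4.66, SE 0.10), AKR1C3 (−3.98, SE 0.09) and AKR1C4, lower with a mean below background in VEPH1 cells, closely related genes whose probes may share signal, encode reductases of steroids and prostaglandins. The chemokine gene CXCL1 (−3.95, SE 0.19), the fatty acid receptor gene CD36 (−3.88, SE 0.10), the lipid droplet gene CIDEC (−3.29, SE 0.16) and ABCA3 (−2.54, SE 0.11) were also lower. So were the laminin gene LAMA4 (−2.34, SE 0.09) and the carbonic anhydrase gene CA12 (−2.30, SE 0.09), and the collagen gene COL1A2, not above background in VEPH1 cells, was at least 17.8-fold lower. The genes most above mock cells were ADAM19 (4.01, SE 0.12), PMEPA1 (3.89, SE 0.22), the adhesion molecule and virus receptor gene CXADR (3.85, SE 0.11), ANXA3 (3.81, SE 0.18), SERPINE2 (3.42, SE 0.12), a protease inhibitor, and SLFN11 (3.37, SE 0.12). The kinase gene SGK1 was at least 10.95-fold, CYFIP2 at least 9.15-fold and RFTN1 at least 8.96-fold higher, against mock cells in which they were not above background. In all, 4044 genes (37.5%) differed in limma, 1996 higher and 2048 lower, of which 435 differed by at least 2-fold. The balance of directions depends on the setting, with 750 higher and 427 lower under a 1.5-fold minimum and 1291 and 1837 among probes above background on all 12 arrays.

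With so many genes changed, 20 of the 26 lists passed fry, which does not compare a list with other genes, and none passed camera with an estimated correlation. Of 8 tested β-catenin/TCF targets, 6 were higher and 1 lower, the same when adjusted over the list alone. CCND1 (2.17, SE 0.09), TNFRSF19 (2.16, SE 0.10) and DKK1, with a mean below background in mock cells, were higher. LEF1 was at least 3.44-fold and AXIN2 at least 1.28-fold higher. The other targets LGR5, RNF43, NKD1, SP5, NOTUM, APCDD1 and BMP4 were not above background. MYC was lower (−0.43, SE 0.10), with a median of 1.76 for the list (fry adjusted p = 1.97e-08; adjusted p = 0.0831 with an estimated correlation). Of 7 tested epithelial genes 5 were higher, the same when adjusted over the list alone. These were EPCAM at least 8.26-fold, the keratin genes KRT8 (1.21, SE 0.10) and KRT7 (0.98, SE 0.14), CDH1 at least 1.26-fold and TJP1 (0.37, SE 0.07), with a median for the list of 0.66, or 0.37 with members below background at their bounds (fry adjusted p = 2.2e-08; adjusted p = 0.0831 with an estimated correlation). Among 8 ovarian carcinoma markers 5 were higher, including MSLN, with a mean below background in mock cells, and PAX8 was lower (−0.55, SE 0.10), the same when adjusted over the list alone (fry adjusted p = 7.67e-08; adjusted p = 0.0831 with an estimated correlation).

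Of the 16 early SMAD2/3 targets, 11 were higher and 1 lower in untreated VEPH1 cells, and 12 higher and 3 lower when adjusted over the list alone (median 0.40, fry adjusted p = 2.13e-05; adjusted p = 0.229 with an estimated correlation). Besides PMEPA1 these included BAMBI, a decoy receptor for the pathway, at least 8.74-fold higher, TGFBI (2.67, SE 0.17), CCN2 (1.91, SE 0.25), SNAI2, at least 2.82-fold higher, and ANGPTL4 (1.31, SE 0.23). The BMP-shared genes went the other way, with 4 of 7 lower and none higher, the same when adjusted over the list alone, led by the Notch and BMP target HEY1 (−1.03, SE 0.09), with a median of −0.30 for the list (fry adjusted p = 9.75e-06; adjusted p = 0.126 with an estimated correlation). Among 10 NF-κB targets and cytokines 6 were lower and 1 higher, the same when adjusted over the list alone. CXCL1, CXCL8 (−1.74, SE 0.37), CXCL2 (−1.53, SE 0.12), CCL20 (−1.41, SE 0.10), the inhibitor gene NFKBIA (−0.97, SE 0.10) and IRAK2 (−0.55, SE 0.10) were lower. IL11 was higher (1.14, SE 0.22), with a median of −0.76 for the list (fry adjusted p = 1.95e-06; adjusted p = 0.0934 with an estimated correlation). Of 19 matrix genes 11 were higher and 3 lower, the same when adjusted over the list alone. COL1A1 (2.27, SE 0.18) and TIMP2 (1.64, SE 0.08) were higher where COL1A2 and COL6A3 (−1.85, SE 0.13) were lower (fry adjusted p = 0.00189; adjusted p = 0.25 with an estimated correlation). Of 15 oxidative stress genes 7 were lower and 1 higher, the same when adjusted over the list alone, including HMOX1 (−1.47, SE 0.24) besides AKR1C2 and AKR1C3 (fry adjusted p = 2.2e-08; adjusted p = 0.0934 with an estimated correlation).

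**Figure D3:**
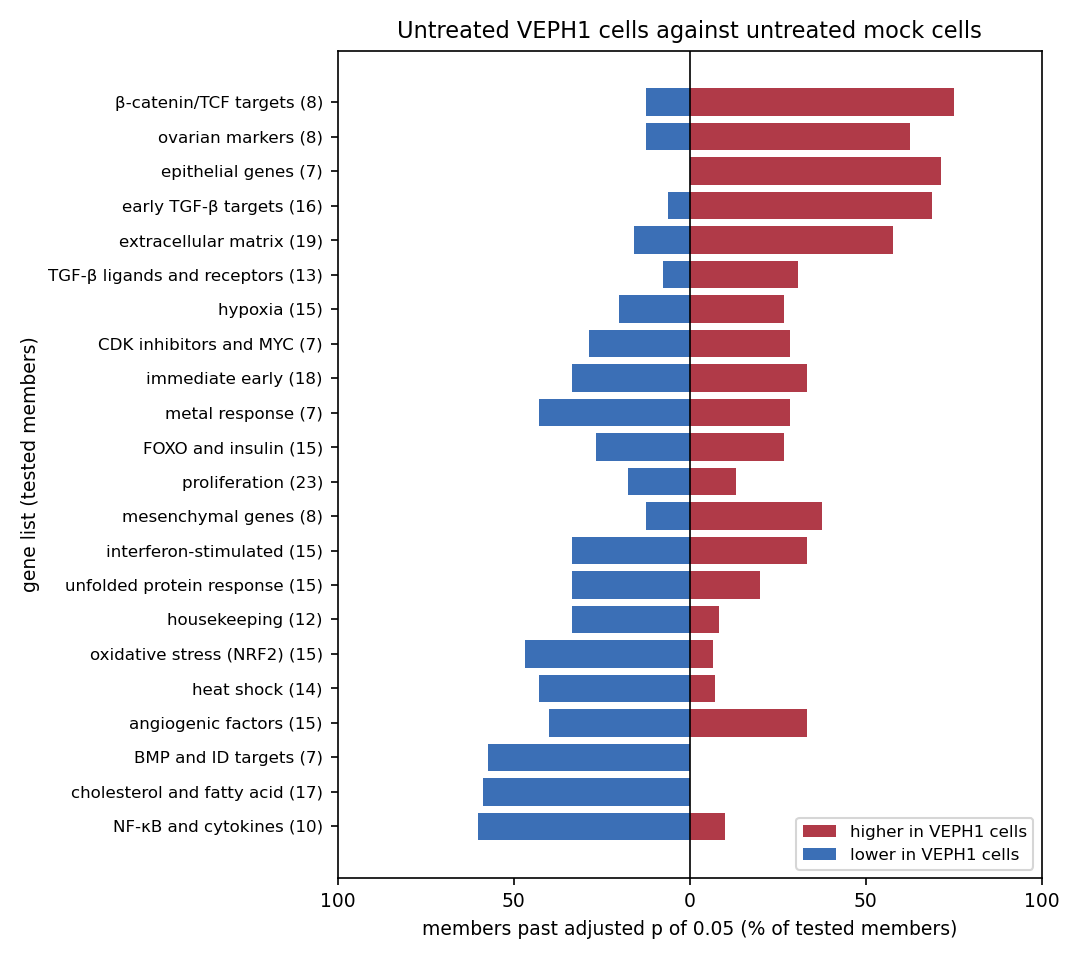
Share of each gene list's tested members (number in parentheses) that were higher (right, % of tested members) or lower (left) in untreated VEPH1 cells than in untreated mock cells at an adjusted p of 0.05 in limma, for lists with at least 7 tested members, ordered by their median change. Of the β-catenin/TCF targets 6 of 8 were higher, and of the NF-κB targets and cytokines 6 of 10 were lower.

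Markers of other cell types were mostly not above background in either line. Of 13 blood cell markers 4 were tested and 2 were higher in VEPH1 cells. These were LCP1, an actin-bundling protein gene also expressed by many carcinoma lines, at least 5.80-fold and CD3D at least 1.07-fold, while PTPRC, CD53 and HBB were not above background (fry adjusted p = 1.66e-08; adjusted p = 0.126 with an estimated correlation). Of 11 fibroblast markers COL1A1 and PDGFRB, at least 1.36-fold, were higher and COL1A2 lower, while LUM, DCN and POSTN were not above background. The median of these 3 was positive (0.69, or 0.45 at the bounds) and fry's direction negative (adjusted p = 0.000138; adjusted p = 0.842 with an estimated correlation). Among embryonic kidney and neural markers TUBB3 (1.08, SE 0.10) and LIN28B, at least 1.09-fold, were higher of 4 tested (fry adjusted p = 3.08e-05; adjusted p = 0.322 with an estimated correlation), and the 1 tested endothelial marker, ESAM, was at least 1.11-fold higher. The counts of these 4 lists were the same when adjusted over each list alone. Of the metallothionein genes MT1F was higher (1.94, SE 0.09) and MT1E (−0.49, SE 0.17), MT1G (−0.48, SE 0.16) and MT2A (−0.33, SE 0.10), which are closely related in sequence, were lower. Of 12 housekeeping genes 4 were lower and 1 higher, with a median of −0.17 (fry adjusted p = 0.00189; adjusted p = 0.324 with an estimated correlation).

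The fourth comparison set the lines against each other after TGF-β. The differences were largely those of the untreated cells. AKR1C2 (−4.78, SE 0.10), CD36 (−3.87, SE 0.10) and CXCL1 (−3.27, SE 0.19) were lower and COL1A2 was at least 22.3-fold lower. ADAM19 (4.16, SE 0.12) and ANXA3 (3.80, SE 0.18) were higher, as were CXADR and BAMBI, whose means in mock cells were below background. SGK1 was at least 12.4-fold, CYFIP2 at least 9.29-fold, RFTN1 at least 8.94-fold and the receptor gene SIRPA at least 7.89-fold higher. NRCAM (−2.27, SE 0.09), A1CF (−2.24, SE 0.16) and LAMA4 (−2.24, SE 0.09) were lower. In all, 3794 genes passed in limma, 1865 higher and 1929 lower, 431 of them by at least 2-fold. Of the genes called in each comparison 2950 were called in both and 2947 in the same direction. These were 1547 higher and 1400 lower, where independent lists of these sizes would share 345 and 366. The 2 comparisons have no array in common, but they set the same 2 kinds of cells against each other. Replicate numbers were also taken to pair the untreated and treated arrays of each line. The overlap thus shows that the differences remained with TGF-β, and it is not an independent test of them.

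After TGF-β the BMP-shared genes differed more than before, with 7 of 7 lower in VEPH1 cells, the same when adjusted over the list alone. The largest differences were in HEY1 (−1.39, SE 0.09), ID2 (−1.28, SE 0.12), SMAD6 (−1.10, SE 0.09) and ID3 (−1.08, SE 0.17), with a median of −1.08 for the list (fry adjusted p = 1.9e-08; adjusted p = 0.0268 with an estimated correlation). Of the 16 early SMAD2/3 targets 6 were higher and 3 lower, against 11 and 1 in untreated cells, with 7 higher and 3 lower when adjusted over the list alone (fry adjusted p = 0.00104; adjusted p = 0.638 with an estimated correlation). PMEPA1 (2.48, SE 0.22) and TGFBI (1.58, SE 0.17) remained higher, and RHOB (−0.54, SE 0.11), TGIF1 (−0.40, SE 0.14) and JUNB, at least 1.35-fold, were lower. The β-catenin/TCF targets again had 6 of 8 higher and 1 lower (fry adjusted p = 1.9e-08; adjusted p = 0.0465 with an estimated correlation), the same when adjusted over the list alone. The ovarian markers had 5 of 8 higher and none lower (fry adjusted p = 4.26e-08; adjusted p = 0.0415 with an estimated correlation), and 6 higher when adjusted over the list alone.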

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

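The test of background correction described here was chosen only after the result it bears on was seen. Each result here is a difference between mock and VEPH1 cells in their response to TGF-β, found by a test of that difference. The response of the 108 response genes was smaller in VEPH1 cells by a median of −0.26 on the log2 scale (permutation p = 0.01). The permutation redistributed the residuals of a model with separate line and treatment effects over the 12 arrays. Of 100 splits 1, the real one, gave a median as large and the highest other was −0.17. A permutation p of 0.01 is the lowest that 100 splits allow. This sets the median apart from the spread between these arrays only. The arrays of a group may be technical replicates, so chance between cultures is not excluded. The BMP-shared list differed by a median of −0.69 (fry adjusted p = 4.77e-05), and again 1 of the 100 splits, the real one, reached it, with −0.51 as the highest other. LIMK2 differed by −0.82 (limma adjusted p = 0.0266). Of the 100 splits 4, the real one among them, called at least 1 gene, a share of 0.04. The count rests on 1 gene, whose call was lost without any 1 of 9 of the 12 arrays. Chance is therefore not held to be excluded for this count. The highest other split called 27 genes, several times the real count, while the median of the other splits was 0. Why that split called so many was not tested. The early SMAD2/3 targets differed by a median of −0.23 (fry adjusted p = 0.124), but 15 of the 100 splits gave a median as large, with −0.33 as the highest other, so chance is not excluded for this list by this test. The redistribution did not keep the replicate numbers together, because they do not pair all 4 groups, although they were taken to pair the samples within each line. With the replicate number as a block the list passed (fry adjusted p = 0.00203). That fit gives all 4 groups the same replicate effects, which the pairing check did not bear out. Its pass therefore does not settle the question, and the list is left open.

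For the smaller response in VEPH1 cells 2 technical explanations were tested. Response genes already shifted in untreated VEPH1 cells, as PMEPA1 and TGFBI were, could leave less room for a further change. Of the 108 response genes 73 were shifted in the direction of the response in untreated VEPH1 cells and 35 were not. Among the 35 not so shifted, the median difference was −0.26, with 33 of 35 smaller in VEPH1 cells. These 35 genes were picked for lacking the shift, so the explanation cannot apply to them. The values show that a smaller response was also seen without such a shift. For the 73 shifted genes, PMEPA1 and TGFBI among them, the explanation was not tested and stays open. Compression of dim genes by background was tested by correcting for it, and after background correction the median difference was −0.46 over 66 response genes, which argues against compression as the cause. What also stays open is whether VEPH1 or another difference between the transfected cells goes with the smaller response. The design cannot separate these, so an effect of VEPH1 may be held only as a hypothesis.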

How the results depend on the processing

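Of 239 alternative values of the 10 main results, 190 kept their direction and their side of the threshold or stayed within 1.5 times the count. The size of the response kept its direction and its call in all 26 of its alternatives (−0.50 to −0.20, fry or camera p from 5.51e-06 to 0.00466). The lowest p came from the 116 genes chosen on mock cells. That choice by itself favours a smaller response in VEPH1 cells, so it is no support. The highest p came from genes chosen on VEPH1 cells, which were only 2. The unadjusted fry p of the early SMAD2/3 targets stayed between 4.59e-07 and 0.00149 in mock cells and under 0.05 in VEPH1 cells (up to 0.0462), where the list did not pass over 26 lists without the block. The counts between untreated lines (4044) and between treated lines (3794) changed by over 1.5 times only with a 1.5-fold minimum, to 1177 and 1119; that minimum gave 44 for TGF-β in mock cells, 1 in VEPH1 cells and 18 for the mean response, by its construction. The replicate block gave 216, 16, 7 and 205 for TGF-β in mock cells, in VEPH1 cells, the difference of the responses and the mean, with every one of the 116, 2, 1 and 108 genes among them. It also changed 17 of 130 list calls, 15 gained and 2 lost, and the gene calls given with both values. Background correction with offset 16 kept 70 of the 116 genes of mock cells, 60 of the 108 of the mean, 3645 of the 4044 and 3436 of the 3794. For TGF-β in VEPH1 cells the count of 2 became 4 with no filter and 1 with every probe, with only the 2 groups compared or with arrays centred. For the difference of the responses the count of 1 became 0 with probes above background on all 12 arrays or with every probe. Array weights gave 184 for mock cells, and background correction with offset 16 gave 66 for the mean. The cause was not tested for these. Leaving out each array in turn gave 62 to 134 genes for mock cells, 1 to 6 for VEPH1 cells, 0 to 2 for the difference and 65 to 123 for the mean, with fewer arrays in each fit. The early target difference ranged from −0.29 to −0.14 and its unadjusted fry p, 0.0238 with all arrays, exceeded 0.05 without untreated mock replicate 2, treated mock replicate 1, untreated VEPH1 replicate 1 or treated VEPH1 replicate 2. The mean count was 67 without untreated mock replicate 3 or treated mock replicate 1, 68 without treated mock replicate 3, and 66 and 65 without untreated VEPH1 replicates 2 and 3. Of 63 named values 60 kept their call with the block, with background correction and without each array in turn, the exceptions being CLDN1, ADAMTS1 and LIMK2 as given above. Of 45 list calls with fry, 7 were kept by camera with an estimated correlation and 38 were lost or reversed. The direction reversed for fibroblast markers between untreated lines (adjusted p = 0.842; 0.762 at the preset correlation) and treated lines (0.919; 0.855) and for the metal response between treated lines (0.919; 0.875), lists whose members moved both ways. Splits of 6 arrays into 3 and 3 are 10, too few for a share under 0.05: the real split called 116, 2, 4044 and 3794 genes, and the highest other called 0 in each of these comparisons, so 1 split of 10 reached the real count. The early targets had 0.49 in mock cells against 0.24 at the highest other split. They had 0.21 in VEPH1 cells, where 2 of 10 splits were as large, with −0.23 as the largest other in size; among the 4 splits that part all 3 pairs the highest other values were 0.22 and 0.11. For the mean response, 1 of 100 redistributions of treatment within lines, the real one, reached 108 genes, with 39 as the highest other. The redistributions did not keep the replicate pairs of a line. They set the count apart from the spread between these arrays only, and chance between cultures is not excluded. Omitting background correction and using the value table are in effect the main setting, and percentile scaling and the slide as a block were not run because scanner values and slides of named samples were not used here. Signal over background limits dim genes: 38.3% of values were above it.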

Other observations

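The test of metallothionein direction was chosen only after its result was seen. Between the untreated lines, several lipid synthesis genes were lower in VEPH1 cells, and single genes of angiogenesis and stress differed in both directions. Of 17 tested cholesterol and fatty acid synthesis genes 10 were lower in VEPH1 cells and none higher, the same when adjusted over the list alone. These include the rate-limiting SQLE (−0.72, SE 0.13), FASN (−0.73, SE 0.10), DHCR7 (−0.71, SE 0.12) and the sterol sensor gene INSIG1 (−0.72, SE 0.08), with a median of −0.43 for the list (fry adjusted p = 0.00321; adjusted p = 0.372 with an estimated correlation). After TGF-β 10 of 17 were again lower. Among 15 angiogenic factors 6 were lower and 5 higher, and the set test did not pass (fry adjusted p = 0.162, or 0.0028 with the replicate block; adjusted p = 1 with an estimated correlation). VEGFA (−1.01, SE 0.18), CXCL8 and FGF2 (−0.53, SE 0.10) were lower, and VEGFC (0.96, SE 0.14) and ANGPT1, with a mean below background in mock cells, higher. Of 14 heat shock genes 6 were lower and 1 higher, with CRYAB (−1.18, SE 0.13) and HSPB1 (−0.51, SE 0.07) among them (fry adjusted p = 0.00109; adjusted p = 0.305 with an estimated correlation).

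Other lists moved both ways. Of 15 interferon-stimulated genes 5 were higher, such as the RNA sensor gene IFIH1 (1.26, SE 0.10), and 5 lower, such as IFIT1 (−0.83, SE 0.12). They had a median of −0.08 and a positive direction in fry (adjusted p = 0.00321; adjusted p = 0.842 with an estimated correlation). Of 15 unfolded protein and amino acid stress genes 3 were higher and 5 lower, and the set test did not pass (fry adjusted p = 0.236; adjusted p = 0.842 with an estimated correlation). PHGDH, of serine synthesis, was higher (2.81, SE 0.17) where TRIB3 (−1.20, SE 0.14), DDIT4 (−1.46, SE 0.12) and ASNS (−0.69, SE 0.14) were lower. Of 8 mesenchymal genes 3 were higher, TAGLN (1.92, SE 0.29), SNAI2 at least 2.82-fold and TWIST1 at least 1.08-fold, and ACTA2 was lower (−0.33, SE 0.12). Their median was −0.05 with a positive direction in fry (adjusted p = 0.0125; adjusted p = 0.833 with an estimated correlation).

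The number of genes that differed between the lines, 4044 untreated, was weighed against 2 explanations. If copy-number differences between the transfected cells were the source of most of them, most would be expected in runs of neighbouring genes shifted one way. Windows of 25 neighbouring tested genes counted if their median exceeded that of any of 1000 shuffled orders, a size of 0.43 on the log2 scale. These windows held 3.96% of the called genes. This argues against runs shifted by more than 0.43 as the source of most called genes. Smaller copy-number shifts could not pass this cut, so copy number stays open as a source of smaller differences. Cadmium given to one kind of cells only would be expected to shift the metallothionein genes one way. Of the 4 that were called, 1 (MT1F) was higher and 3 were lower. Of the 7 genes of the metal response list 2 were higher and 3 lower, with a median of −0.02 and a positive direction in fry (adjusted p = 0.000507; adjusted p = 0.842 with an estimated correlation). Other genes that cadmium can induce leaned lower in VEPH1 cells, such as HMOX1 (−1.47, SE 0.24) and the heat shock genes (6 of 14 lower, 1 higher), a list that did not pass with an estimated correlation. Most of these called genes were lower in VEPH1 cells, but MT1F was higher and the metal response list moved both ways. The labels do not give the arrays that received cadmium, so this explanation stays open for either kind of cells. VEPH1 itself, the selection of transfected cells and drift between them stay open as untested.

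The windows that did pass lay in few places, by the gene order of the RefSeq table. On chromosome 16, 3 stretches of 33, 43 and 92 tested genes had medians of 0.41, 0.40 and 0.48 in untreated VEPH1 minus mock cells, with 19, 31 and 62 genes called higher and 1, 3 and 0 lower; the longest ran from PRMT7 to MVD. On the TGF-β treated arrays, which were not used to find them, 18, 30 and 66 of these genes were called higher and 1, 3 and 0 lower, with medians of 0.29, 0.38 and 0.48. A stretch of 39 genes on chromosome 7, from BUD23 to PCLO, had a median of −0.41, with 25 genes lower and 1 higher (19 and 1 on the treated arrays, where the median was smaller, −0.27). A stretch of 25 genes on chromosome 1, from YOD1 to NSL1, had a median of 0.43 with 17 genes higher and 1 lower, and of 0.30 with 14 higher and 1 lower on the treated arrays. A copy-number difference between the cells may underlie these stretches, which hold 3.96% of the called genes; DNA was not measured. The metallothionein genes MT1E and MT1F lie in the stretch of 43 genes.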
